A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

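RNA that carries NAD+ at its 5' end was captured from the haploid budding yeast strain BY4742, an alpha-mating-type strain with deletions in the HIS3, LEU2, LYS2 and URA3 genes. Per the labels' protocols, cells in mid-log growth came from a minimal medium (yeast nitrogen base, a complete set of amino acids and dextrose) or from the rich medium YEPD. Total RNA was treated with DNase and was neither depleted of ribosomal RNA nor fragmented, per the labels' protocols. It was incubated with an alkyne (4-pentynol) and with ADP-ribosylcyclase (ADPRC), the enzyme that exchanges the nicotinamide of an NAD cap for the alkyne, or without the enzyme (mock). Biotin was then joined to the alkyne by copper-catalysed click chemistry, the RNA was bound to streptavidin beads, and cDNA was made on the beads and sequenced on an Illumina instrument, per the labels' protocols. The 12 libraries form 4 groups of 3: mock and ADPRC in minimal medium, and mock and ADPRC in YEPD. The labels number all 3 YEPD ADPRC libraries, but the name of a column of values in this group carries no replicate number. The library of that column is called unnumbered, since its number would follow only by elimination from the other columns of the group. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical only.

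The deposited table holds 1 column per library and no column of any other sample (0). Its values are a signal that the authors made by dividing the read count of each gene by 1 factor per library, per the file headers and as checked on the values: in all 12 columns every value was a whole multiple of the smallest step of its library (tolerance 0.01 reads). In the YEPD mock replicate 2 column that step was 1.00, so near 1 that the column was left out of the tools that need counts. FastQC, Trimmomatic, Bowtie, HTSeq and DESeq are named in the submitters' processing notes. Their versions, order and settings, the genome build, the annotation, the use of strand in counting and the handling of reads with several positions are not given in the sources used here. The table lists 6608 identifiers, 1 of them duplicated, hence 6607 distinct ones, and 130 were 0 in every library. Gene symbols, lengths and neighbours came from the RefSeq R64 gene table, which matched 5919 of the identifiers and left 688 unmatched, mostly dubious open reading frames. Lengths are spans from start to stop with introns included, and 96.9% were multiples of 3, so they are called coding lengths. No coordinate was used beyond the order of neighbours.

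Recovered reads ranged from 3246900 to 13958188 per library. A gene with 0 reads in a library could still hold up to 3 reads' worth of signal, a floor of 4.28 to 5.42 normalized counts in minimal mock, 1.60 to 1.92 in minimal ADPRC, 2.18 to 3.39 in YEPD ADPRC and 2.81 to 3.87 in YEPD mock libraries. Such floors cover counting error only, since PCR copies of 1 molecule cannot be told apart. A fold against a group at 0 in all of its libraries is given as a lower bound against the mean floor of 3 reads per library.

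Values were transformed as log2(value + 1). Genes with a mean of at least 10 over the 12 libraries were kept (5490 genes), and 1 model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 with a trend in the prior variance and robust estimation. The 5 contrasts were ADPRC against mock in minimal medium, ADPRC against mock in YEPD, the difference between these, minimal against YEPD in mock libraries, and minimal against YEPD in ADPRC libraries. P-values were adjusted within each contrast by the Benjamini-Hochberg method at 0.05 and are two-sided. Errors beside log2 changes are the standard errors of limma, and those beside means are standard deviations, with n = 3 libraries per group throughout. Overlap between gene sets was tested with Fisher's exact test among the tested genes.

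From memory of yeast biology, 27 gene lists were fixed before the data were examined, as were the groups, contrasts, threshold and named-gene rule. Of these, 21 had at least 3 tested members: mitochondrially encoded genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation, translation factors, glycolysis and ethanol formation, the tricarboxylic acid cycle, amino acid biosynthesis, sulfur and methionine metabolism, thiamine metabolism, the phosphate starvation response, iron uptake, NAD biosynthesis, decapping and 5'-to-3' decay, heat shock proteins and chaperones, histones, ribosome biogenesis, hexose transporters, alpha-cell genes, a-cell genes and sporulation genes. The list of deleted genes (1) had fewer than 3 tested members and was read gene by gene. Lists of small nucleolar and spliceosomal RNAs, nuclear tRNAs, mitochondrial tRNAs, nuclear ribosomal RNAs and other RNA polymerase III transcripts (5 lists) had no member in the table. Each list was compared with all other tested genes by camera, with a preset correlation of 0.01 between genes and again with an estimated one, and adjusted over the 21 lists of a contrast. Counts per list are given from the adjustment over all genes and from one over the list alone.

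Genes were named by a rule fixed in advance. For ADPRC against mock in each medium it takes the 10 largest positive and 10 largest negative changes past the threshold with all 3 ADPRC values on 1 side of the 3 mock values. For the media it takes 5 per direction, and for the difference between media 5 per direction without the condition on overlap. It adds up to 4 members of each list with the highest mean over the 12 libraries, every measured mitochondrially encoded, alpha-cell and a-cell gene, and the deleted genes. Near-identical copies and genes that overlap others are called uncertain.

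Alternatives planned in advance were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, TMM factors, the same total per library, quantile normalization, fitting only the groups compared, the replicate number as a block, leaving out each library, weights per library, no trend and no robust estimation, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on recovered reads without YEPD mock replicate 2. After the data were seen, 2 were added: removing from each library a loess trend (span 0.5) of log2 value on log2 gene length, and leaving out genes that can overlap another on the opposite strand. DESeq2 was used here only in this way.

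The steps were tested on simulated counts with 200 genes changed. In the simulation of ADPRC against mock in minimal medium (5489 genes), limma recovered 39.4% of genes changed 1.5-fold, 83.6% changed 2-fold and 100% changed 4-fold, and 8.07% of its calls were false. For YEPD (5482 genes) it recovered 46.3%, 86.4% and 98.5%, with 2.55% false. For the difference between media (5480 genes) it recovered 13.6%, 65.7% and 95.4%, with 1.71% false. For minimal against YEPD it recovered 44.8%, 89.6% and 98.5% in mock libraries (5489 genes, 8.33% false) and 50.7%, 85.1% and 98.5% in ADPRC libraries (5487 genes, 3.70% false). The simulated groups shared 1 spread per gene and held no library that stands apart, as YEPD ADPRC replicate 2 does in the data. The shares recovered may thus be too high for the contrasts that use that library, the difference between media among them. A simulated trend with length made 92.3% of the calls false in minimal medium (5506 genes), and removing it left 4.00% false (5438 genes). That trend was steeper than the one between the real groups. It was also an exact function of the lengths used to remove it, so the removal may work less well on real RNAs. Figures were drawn with matplotlib 3.10.9. Raw reads were not used here.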

Results

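To determine which yeast RNAs are captured through an NAD+ cap, RNA that gained an alkyne in the presence of ADPRC was sequenced beside RNA taken through the same steps without the enzyme, in BY4742 cells grown in minimal medium or in YEPD. Each of the 4 groups held 3 libraries. Minimal mock libraries held 3246900, 3937618 and 3358689 reads in replicates 1, 2 and 3, and minimal ADPRC libraries 7959385, 6727168 and 7122417. YEPD mock libraries held 13820148, 13531236 and 11700161 reads. YEPD ADPRC libraries held 13370410 (unnumbered), 13958188 (replicate 2) and 12051316 (replicate 3). A difference seen after ADPRC is one of enrichment over mock, not a measure of the share of an RNA that is capped.

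Ribosomal RNA had not been removed, and many reads fell on open reading frames annotated within the repeated ribosomal DNA. Their share was 52.9% ± 2.02 in minimal mock, 31.7% ± 1.34 in minimal ADPRC, 80.8% ± 1.10 in YEPD mock and 75.2% ± 8.15 in YEPD ADPRC libraries (SD, n = 3). The share was 65.9% in YEPD ADPRC replicate 2 against 79.4% and 80.5% in the other two. Reads outside these frames came to 1.66 ± 0.244, 4.97 ± 0.463, 2.51 ± 0.357 and 3.29 ± 1.29 M per library (M, mega; SD, n = 3) in the same order of groups. The first principal component, with 76.3% of the variance, parted the media. Watson-strand frames of the ribosomal DNA took 0.0383% of the reads in minimal mock and 62.3% in YEPD mock libraries. Along this component a difference in counting or library preparation thus cannot be told apart from growth medium. The second, with 13.4%, was higher in ADPRC than in mock libraries of each medium. It ran from -18.5 to -16.3 in minimal mock, 11.3 to 17.0 in minimal ADPRC and -10.9 to -8.4 in YEPD mock libraries. YEPD ADPRC replicate 2 (36.9) lay apart from the other libraries of its group (3.36 and -0.53), in the direction away from mock.

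**Figure D1:**
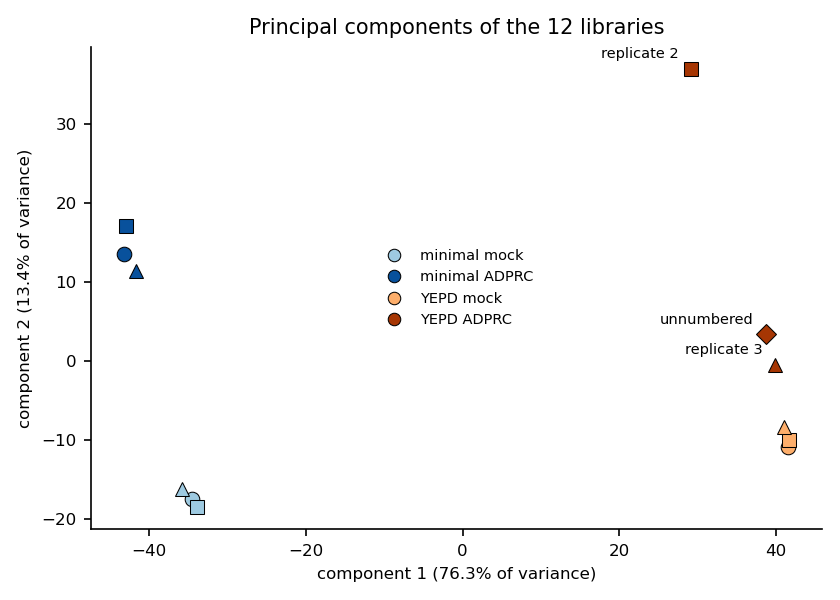
Principal components of log2(value + 1) over the tested genes, with 1 point per library, the first component (76.3% of the variance) on the x axis and the second (13.4%) on the y axis, for mock and ADPRC libraries of both media. The media separate along x, where a difference in counting or library preparation cannot be told apart from growth medium. Along y ADPRC libraries lie above mock libraries of the same medium, and YEPD ADPRC replicate 2 lies apart from the others of its group.

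Mitochondrially encoded RNAs went both ways after ADPRC. COX2 (Q0250), which encodes subunit II of cytochrome c oxidase, rose in minimal medium from 213 ± 52.6 to 661 ± 13.6 normalized counts (log2 change 1.65 ± 0.17, adjusted p = 0.000217) and in YEPD from 236 ± 40.1 to 714 ± 101 (1.60 ± 0.17, adjusted p = 0.00012). OLI1 (Q0130), the gene of ATP synthase subunit 9, rose by 1.04 ± 0.15 in minimal medium (443 ± 60.1 to 912 ± 115, adjusted p = 0.00117) and by 1.60 ± 0.15 in YEPD (378 ± 55.6 to 1145 ± 162, adjusted p = 4.55e-05). COB (Q0105), for cytochrome b, fell in minimal medium from 121 ± 28.3 to 44.0 ± 5.82 (-1.42 ± 0.26, adjusted p = 0.0031) and in YEPD from 143 ± 23.6 to 75.3 ± 29.0 (-0.98 ± 0.26, adjusted p = 0.0403). SCEI (Q0160), a homing endonuclease frame in the intron of the mitochondrial large ribosomal RNA gene, fell from 105 ± 13.5 to 41.4 ± 7.11 (-1.33 ± 0.26, adjusted p = 0.00553) and from 179 ± 17.6 to 92.1 ± 38.1 (-1.05 ± 0.26, adjusted p = 0.0346). The other oxidase subunits COX1 (Q0045) and COX3 (Q0275) and the ATP synthase subunit ATP6 (Q0085) fell in minimal medium by 0.81, 1.07 and 1.19 (adjusted p = 0.0268, 0.0188 and 0.0169). In YEPD their changes were -0.85 ± 0.24, -0.93 ± 0.29 and -1.14 ± 0.31, past no threshold (adjusted p = 0.0588, 0.0806 and 0.0507), and the difference between media was past the threshold for no mitochondrial gene. Of 28 mitochondrial identifiers in the table, 7 were abundant enough to test. As a list they had a median change of -1.07 and a mean of -0.44 in minimal medium (2 higher, 5 lower, and the same counts adjusted over the list alone; camera adjusted p = 0.57), and -0.93 and -0.25 in YEPD (2 higher, 2 lower, and 2 and 5 adjusted over the list alone; camera adjusted p = 0.638). Both medians stayed negative under each scaling tried, and that of YEPD was -0.48 without ADPRC replicate 2.

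Several calls for the mitochondrial genes that fell ended when 1 of several libraries was left out, though those of COB and SCEI in minimal medium held without each library. In minimal medium the COX1 call ended without mock replicate 1 (adjusted p = 0.075) or 3 (0.0928), or ADPRC replicate 1 (0.0683), 2 (0.0922) or 3 (0.0588). The COX3 call ended without mock replicate 1 (adjusted p = 0.051) or 3 (0.0715), or ADPRC replicate 1 (0.0612) or 2 (0.0713), and the ATP6 call without mock replicate 1 (0.0505) or 3 (0.0617), or ADPRC replicate 2 (0.0781). In YEPD the COB call ended without mock replicate 1, 2 or 3 (adjusted p = 0.17, 0.0648 and 0.129), as did the SCEI call (0.143, 0.0828 and 0.104). Leaving out the unnumbered YEPD ADPRC library, replicate 2 or replicate 3 instead brought COX1 (adjusted p = 0.0479, 0.042 and 0.0101), COX3 (0.0384, 0.0329 and 0.0243) and ATP6 (0.0409, 0.0421 and 0.0112) past the threshold in YEPD. Without replicate 2 their changes were smaller, at -0.48, -0.45 and -0.67, as was that of SCEI (-0.65). With the trend in gene length removed, COX2 kept a change of 1.32 ± 0.20 in minimal medium and 1.35 ± 0.20 in YEPD, OLI1 had 0.52 ± 0.24 (adjusted p = 0.175) and 1.12 ± 0.24 (0.034), and COX1, whose length includes introns, had 0.14 in minimal medium (0.556). The YEPD calls of COB (-0.44, adjusted p = 0.211) and SCEI (-1.32, 0.071) ended then. Fitting only the YEPD libraries (COB 0.187, SCEI 0.195) and fitting without trend and robust estimation (0.06 and 0.0546) also ended them, as edgeR did that of SCEI (0.0593). With the same total COX1 was at -0.38 in minimal medium (0.112). In YEPD ATP6 passed the threshold with a pseudocount of 8 (0.0426), a mean of at least 50 (0.0494) and TMM (0.0496), COX1 with DESeq2 (0.0426), and COX1, COX3 and ATP6 with weights per library (0.0162, 0.0155 and 0.0098), where their changes were -0.51, -0.45 and -0.73.

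**Figure D2:**
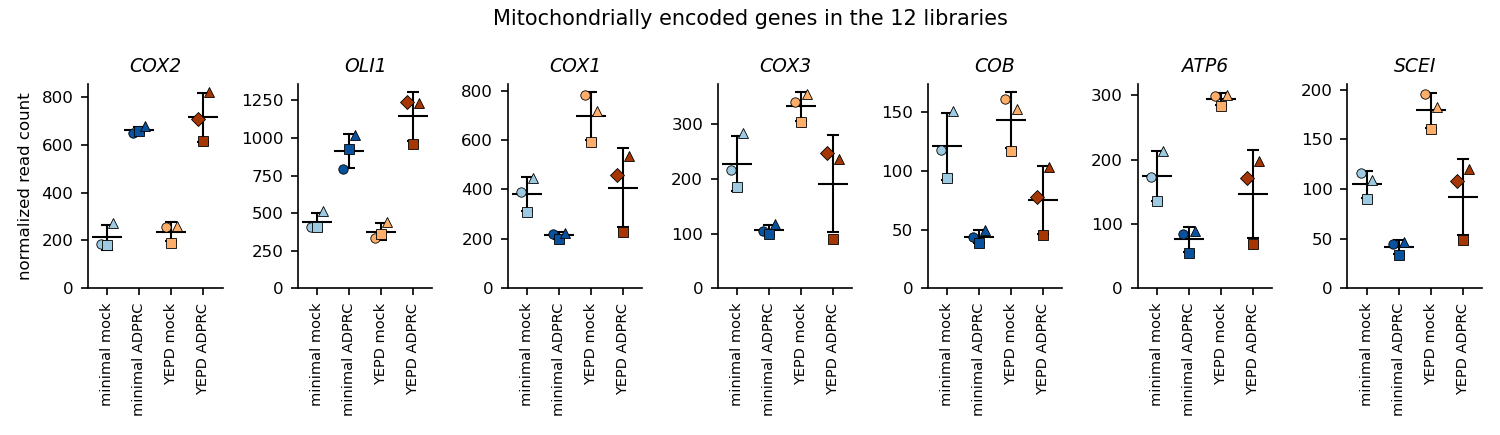
Normalized read count (y axis) of 7 mitochondrially encoded genes in the 4 groups, with 1 point per library, its shape showing the replicate, a line at the mean and bars of 1 SD. COX2 and OLI1 lie higher in ADPRC than in mock libraries of both media, and the other 5 genes lie lower on average.

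To find RNAs enriched by the enzyme in minimal medium, ADPRC libraries were compared with mock libraries there. The largest increases were in short genes: HUG1 (YML058W-A), a gene induced by DNA damage, rose from 2.74 ± 2.69, under the floor of 3 reads, to 16.0 ± 6.46 (2.46 ± 0.57, adjusted p = 0.0105). SHU2 (YDR078C), which acts in recombinational repair, rose from 5.24 ± 3.37 to 21.5 ± 3.05 (2.01 ± 0.44, adjusted p = 0.00809, and 0.0598 with quantile normalization). The ribosomal protein gene RPS20 (YHL015W) rose from 3758 ± 276 to 14585 ± 1421 (1.95 ± 0.43, adjusted p = 0.00832), the splicing factor gene DIB1 (YPR082C) from 22.0 ± 5.34 to 72.4 ± 7.97 (1.70 ± 0.21, adjusted p = 0.000816), and the methionine sulfoxide reductase gene MXR1 (YER042W) from 48.2 ± 4.67 to 152 ± 21.3 (1.63 ± 0.23, adjusted p = 0.00117). Next to COX2 stood BLI1 (endosomal BLOC-1 complex), ATG44 (mitochondrial fission in mitophagy), IMP1 (the inner membrane peptidase that processes Cox2) and the uncharacterized YJR112W-A, which rose by 1.69, 1.66, 1.65 and 1.63. The largest decreases were in open reading frames that overlap ribosomal DNA and cannot be told from it, YLR154W-F (-2.14), YLR154W-B (-1.92), RRT15 (-1.81), YLR154W-A (-1.79), YLR154W-E (-1.62) and TAR1 (-1.27), beside COB, SCEI, YMR013W-A (-1.30) and the dihydroxyacetone kinase gene DAK2 (-1.26 ± 0.36, adjusted p = 0.022). The DAK2 call ended without mock replicate 3 (adjusted p = 0.0752) or ADPRC replicate 2 (0.0902), and the TAR1 call without mock replicate 2 (0.0522) or ADPRC replicate 1 (0.0563). A pseudocount of 8 (0.0513) and edgeR (0.0793) also ended the DAK2 call. Quantile normalization ended those of TAR1 (0.0889) and YMR013W-A (0.0703), and fitting only the minimal-medium libraries that of TAR1 (0.0507). With the trend in gene length removed the BLI1 call ended (1.19, adjusted p = 0.0527), and without mock replicate 1 BLI1 was at 1.06. By the rule, all 3 ADPRC values of each of these genes lay on 1 side of the 3 mock values.

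Across all genes, 780 were higher and 803 lower after ADPRC in minimal medium (limma, of 5490), of which 161 and 24 changed over 2-fold. The median change among those called was 0.73 and -0.54. Groups did not overlap for 54.8% of genes, where chance gives 10%. The balance of directions rests on the scaling, since with the same total per library 2492 genes were higher and 51 lower, the median of all genes then being 0.44. That total includes the ribosomal DNA frames, whose share was 52.9% in minimal mock and 31.7% in minimal ADPRC libraries. The counts higher and lower fell to 486 and 360 without mock replicate 1, 444 and 306 without mock replicate 2, and 543 and 452 without mock replicate 3. They were 363 and 275 without ADPRC replicate 1, 337 and 211 without replicate 2, and 469 and 469 without replicate 3. Fitting only the minimal-medium libraries gave 1291 and 1259, and weights per library 1364 and 1360. Removal of the trend in gene length gave 389 and 425, with 307 of 777 higher and 251 of 792 lower genes still called.

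Among gene families in minimal medium, genes of cytosolic ribosomal proteins had a positive median in each scaling. Of 137 tested, 71 were higher and 0 lower (81 and 1 adjusted over the list alone), with a median of 0.60. The camera call (adjusted p = 2.75e-17) was lost with an estimated correlation (0.971). With the trend in gene length removed the median was 0.26, with 38 higher and 9 lower (adjusted p = 1.23e-07). The number higher was 41 and 44 without mock replicates 1 and 2, and 39, 39 and 46 without ADPRC replicates 1, 2 and 3. The abundant members RPL4A (0.35 ± 0.24), RPL3 (0.22 ± 0.17), RPL4B (0.37 ± 0.24) and RPL5 (-0.13 ± 0.11) were not past the threshold. Of 73 mitochondrial ribosomal protein genes 19 were higher and 0 lower (18 and 0 adjusted over the list alone; median 0.31, adjusted p = 3.04e-05, and 0.971 with an estimated correlation). MRPS12 was among them (0.66 ± 0.14, adjusted p = 0.00754). With the length trend removed their median was 0.02, with 4 higher and 5 lower, they were not called (adjusted p = 0.915), and the MRPS12 call ended (0.21, adjusted p = 0.26). The number higher was 10 without mock replicate 3 and 11, 8 and 12 without ADPRC replicates 1, 2 and 3. Of 41 nuclear genes of oxidative phosphorylation 18 were higher and 5 lower (21 and 5 adjusted over the list alone; median 0.41, adjusted p = 0.00158, and 0.971 with an estimated correlation). With the length trend removed this median was -0.0033, with 4 higher and 5 lower, and the call ended (adjusted p = 0.952). There were 10, 10 and 12 higher without mock replicates 1, 2 and 3, and 8, 9 and 11 without ADPRC replicates 1, 2 and 3. The NADH dehydrogenase gene NDE1 went the other way (-0.49 ± 0.11, adjusted p = 0.00776), though with the same total its change was -0.06.

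Of the other lists in minimal medium, none was called by camera. Histone genes had 3 higher and 0 lower of 10 (4 and 0 adjusted over the list alone, median 0.39, adjusted p = 0.0642), with HTB1 at 1.03 ± 0.25 (1262 ± 107 to 2580 ± 57.5, adjusted p = 0.0125). Alpha-cell genes, which mark the mating type, had 4 higher and 0 lower of 7 (6 and 1 adjusted over the list alone, median 0.75, adjusted p = 0.0774), with the pheromone gene MF(ALPHA)2 at 0.75 ± 0.12, or 0.25 with the length trend removed (adjusted p = 0.348). NAD biosynthesis had 6 higher and 1 lower of 23 (the same adjusted over the list alone). Its median was 0.06. Decapping and 5'-to-3' decay had 2 higher and 2 lower of 15 (the same adjusted over the list alone), with a median of -0.03. Its exonuclease gene XRN1 fell by 0.69 ± 0.19 (adjusted p = 0.0181), a call that ended without mock replicate 2 (0.0685), ADPRC replicate 1 (0.058) or ADPRC replicate 2 (0.0665). XRN1 was at -0.13 with the length trend removed (adjusted p = 0.237) and at -0.26 with the same total (0.181). Phosphate starvation genes had 4 higher and 4 lower of 14 (6 and 4 adjusted over the list alone, median 0.15), the transporter gene PHO84 falling by 0.73 ± 0.14 (adjusted p = 0.00431). The tricarboxylic acid cycle had 2 higher and 2 lower of 15 (the same adjusted over the list alone, median 0.07), its subunit gene KGD1 at -0.40 ± 0.09 (adjusted p = 0.011), or 0.03 with the same total and -0.02 with the length trend removed (0.879). Counts higher and lower were 4 and 4 of 34 for translation factors, 1 and 4 of 20 for glycolysis and ethanol formation, 9 and 6 of 52 for amino acid biosynthesis, 3 and 2 of 24 for sulfur and methionine metabolism, 0 and 1 of 18 for thiamine metabolism, and 3 and 2 of 19 for iron uptake. They were 1 and 5 of 25 for heat shock proteins and chaperones, 4 and 8 of 44 for ribosome biogenesis, 0 and 1 of 14 for hexose transporters, 0 and 0 of 3 for a-cell genes and 0 and 0 of 5 for sporulation genes. Adjusted over the list alone these stayed the same except for translation factors (4 and 2), thiamine metabolism (0 and 0) and hexose transporters (0 and 0). Medians of these lists lay between -0.26 (a-cell genes) and 0.51 (sporulation genes). The medians of the sulfur, iron, decapping, heat shock, ribosome biogenesis, hexose and a-cell lists were negative but positive with the same total, and those of translation factors, glycolysis and thiamine were positive but negative after quantile normalization. The camera test ran downward for glycolysis and thiamine metabolism against positive medians (0.14 and 0.02), and the sulfur list had a median of -0.03 and a mean of 0.08. With HXT15 and HXT16, 0 in minimal ADPRC libraries, set to their bounds, the hexose median went from -0.17 to -0.04.

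**Figure D3:**
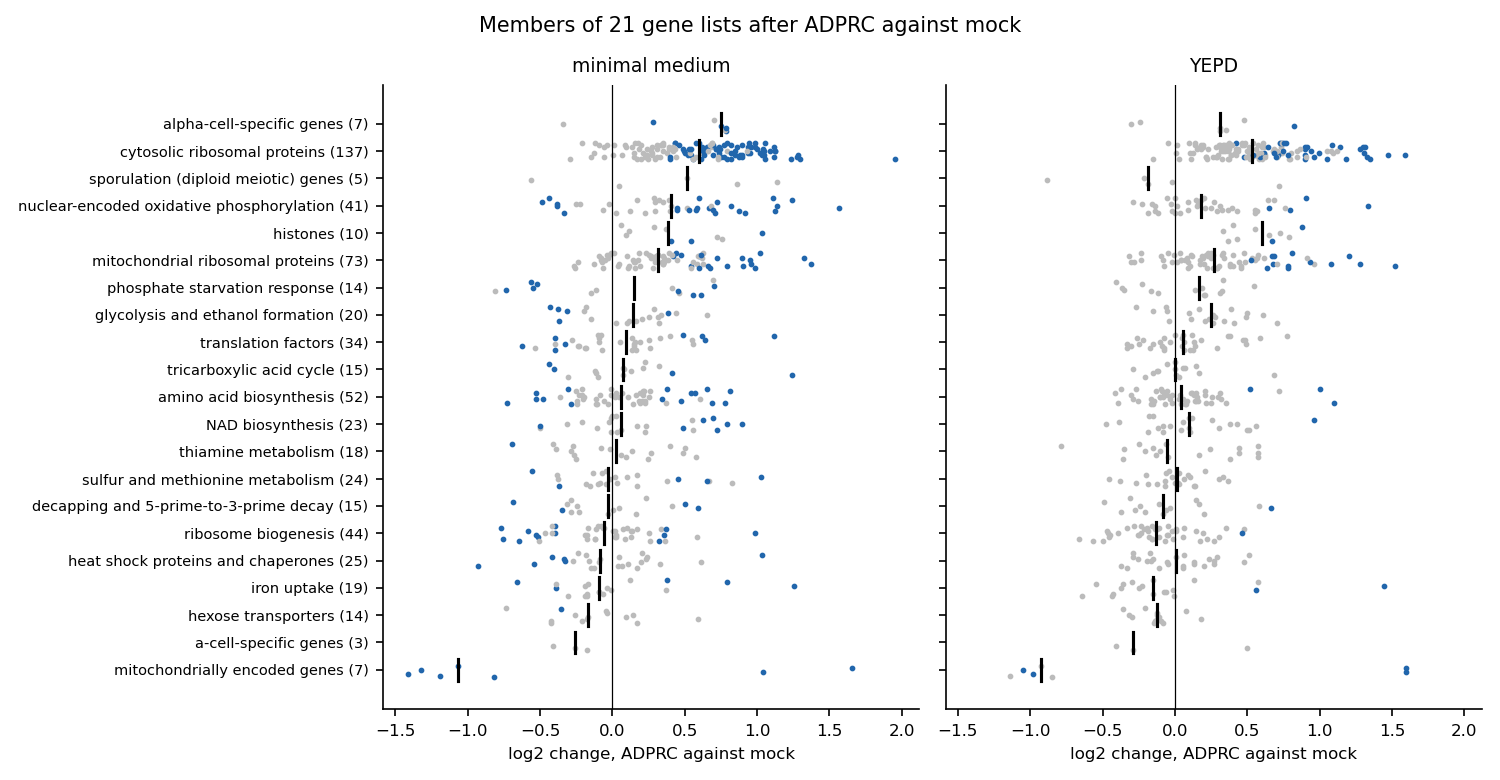
Log2 change of ADPRC against mock (x axis) of each member of 21 gene lists, with the number of members in parentheses, in minimal medium and in YEPD; blue points are past the threshold, gray points are not, and a black tick marks the list median. Cytosolic ribosomal protein genes lie mostly above 0 in both media, with medians of 0.60 and 0.53, under each scaling.

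The same question was asked in YEPD. Beside COX2 and OLI1, the largest increases were in the ribosomal protein genes RPL37B (YDR500C, 1.59 ± 0.34, adjusted p = 0.0161) and RPS29B (YDL061C, 1.48 ± 0.19, adjusted p = 0.000611). Close to these were the coenzyme Q-binding protein gene COQ10 (YOL008W, 31.2 ± 5.46 to 93.9 ± 7.25, 1.57 ± 0.17, adjusted p = 0.00015) and the mitochondrial ribosomal protein gene MRPS12 (YNR036C, 111 ± 20.8 to 321 ± 46.8, 1.52 ± 0.14, adjusted p = 4.55e-05). The acetyltransferase subunit gene MAK31, the transcription factor subunit gene TAF9, DIB1 and YJR112W-A rose by 1.47, 1.47, 1.46 and 1.45. COX2, DIB1 and YJR112W-A were thus among the 10 largest increases of both media. RPL37B reached 3967 ± 3112 normalized counts from 1095 in mock libraries, and its call ended without mock replicate 1 (adjusted p = 0.0791) or 2 (0.0689), with edgeR (0.0551) and with the trend in gene length removed (0.0584). Without ADPRC replicate 2 its change was 0.99. Fitting only the YEPD libraries ended the calls of RPL37B (0.17), MAK31 (0.0605) and YJR112W-A (0.0527). The 10 largest decreases by the rule were YNL203C (-1.56), SCEI, COB, YLR285C-A (-0.94), the spore wall gene ADY3 (-0.80), the RNA polymerase III factor gene TFC1 (-0.75 ± 0.17, adjusted p = 0.0183), YOR192C-C (-0.73), YIL060W (-0.72), YHR145C (-0.71) and YCR018C-A (-0.65). YNL203C, YHR145C and YCR018C-A have no match in RefSeq, and YOR192C-C, YIL060W and YHR145C have nearly the same values, so all of these are uncertain. Without YEPD mock replicate 1 each of these calls ended (adjusted p from 0.0633 for TFC1 to 0.199 for YOR192C-C). Without mock replicate 2 YNL203C (0.0698), YLR285C-A (0.0975), ADY3 (0.0826), TFC1 (0.05002), YOR192C-C (0.107), YIL060W (0.117), YHR145C (0.122) and YCR018C-A (0.133) ended. Without mock replicate 3 ADY3 (0.126), TFC1 (0.0815), YOR192C-C (0.0799), YIL060W (0.0815), YHR145C (0.0838) and YCR018C-A (0.0981) ended, and without ADPRC replicate 2 ADY3 (0.063) and YCR018C-A (0.0923), while YIL060W and YHR145C were each at -0.47. Fitting only the YEPD libraries ended each of the 10 calls (0.065 to 0.203), and the same total those of all but COB and SCEI (0.0741 to 0.124). With edgeR those of all but COB and TFC1 ended (0.0576 to 0.146), and with DESeq2 those of YIL060W, YHR145C and YCR018C-A (0.0539 to 0.0828). Quantile normalization ended those of YNL203C (0.098) and YHR145C (0.0505), and a pseudocount of 8 that of YNL203C (0.0794). YOR192C-C, YIL060W, YHR145C and YCR018C-A ended with no filter (0.0523 to 0.055) and without trend and robust estimation (0.0575 to 0.0705). With the trend in gene length removed the calls of ADY3 (-0.59, adjusted p = 0.0707), YOR192C-C (-1.20, 0.0772) and YIL060W (-1.11, 0.0669) ended, the changes of the last 2 being larger than before.

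In YEPD 270 genes were higher and 30 lower, of which 64 and 2 changed over 2-fold, and the median change among those called was 0.78 and -0.54. Groups did not overlap for 32.2% of genes (chance gives 10%). Counts higher and lower were 107 and 0 without mock replicate 1, 139 and 0 without mock replicate 2, and 189 and 4 without mock replicate 3. They were 290 and 109 without the unnumbered ADPRC library, 339 and 75 without ADPRC replicate 2, and 617 and 492 without ADPRC replicate 3. Fitting only the YEPD libraries gave 46 and 0, and weights per library 532 and 283. On recovered reads edgeR gave 131 and 3 and DESeq2 202 and 15. With the trend in gene length removed the counts were 144 and 29, and of the genes called before that have a length 126 of 270 higher and 4 of 27 lower were still called. The counts were, with the same total per library 307 and 2, after quantile normalization 267 and 50, and without trend and robust estimation 239 and 15.

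Genes of cytosolic ribosomal proteins had a positive median in YEPD as well, in each scaling, with 35 higher and 0 lower of 137 (78 and 0 adjusted over the list alone), a median of 0.53 and 135 positive values (camera adjusted p = 1.04e-26, and 0.893 with an estimated correlation). The number higher was 62 without ADPRC replicate 2, where the median was 0.24, 85 without ADPRC replicate 3, and 14 and 15 without mock replicates 1 and 2. With the trend in gene length removed the median was 0.28, with 22 higher and 0 lower (adjusted p = 5.78e-18). Mitochondrial ribosomal protein genes had 13 higher and 0 lower of 73 (24 and 0 adjusted over the list alone; median 0.27, adjusted p = 8.47e-08, and 0.893 with an estimated correlation), with 22 higher without ADPRC replicate 3 and 5 and 7 without mock replicates 1 and 2, and a median of 0.17 without ADPRC replicate 2. Histone genes had 2 higher and 0 lower of 10 (4 and 0 adjusted over the list alone; median 0.60, adjusted p = 0.000211, and 0.893 with an estimated correlation). HHT2 (977 to 1794, 0.88 ± 0.15, adjusted p = 0.00304) and HTB2 (1080 to 1737, 0.67 ± 0.11, adjusted p = 0.00303) were those 2 members, and 6 were higher without ADPRC replicate 3 and 3 without ADPRC replicate 2, where the median was 0.24. Nuclear genes of oxidative phosphorylation had 4 higher and 0 lower of 41 (7 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.025, and 0.893 with an estimated correlation), with a median of -0.04 without ADPRC replicate 2 (adjusted p = 0.65), 0.34 without the unnumbered ADPRC library, and 0.29 with 9 higher without ADPRC replicate 3. MF(ALPHA)2 rose from 508 to 903 (0.83 ± 0.12, adjusted p = 0.00126), the 1 member called higher in the alpha-cell list (1 of 7 also adjusted over the list alone; median 0.31, adjusted p = 0.638). With the length trend removed the calls of mitochondrial ribosomal proteins (-0.02, adjusted p = 0.422), histones (0.18, 0.116) and oxidative phosphorylation (-0.12, 0.224) ended, as did those of HHT2 (0.47, 0.0603), HTB2 (0.26, 0.105) and MF(ALPHA)2 (0.40, 0.233). Fitting only the YEPD libraries also ended those of HHT2 (0.0958) and HTB2 (0.0899). No other list was called in YEPD. Amino acid biosynthesis had 3 higher and 0 lower (the same adjusted over the list alone; median 0.04), iron uptake 2 and 0 (3 and 1 alone; -0.15), NAD biosynthesis 1 and 0 (the same alone; 0.09), decapping and 5'-to-3' decay 1 and 0 (the same alone; -0.08), and ribosome biogenesis 1 and 0 (0 and 0 alone; -0.13, adjusted p = 0.087). The lists with 0 higher and 0 lower had medians of 0.05 for translation factors, 0.25 for glycolysis and ethanol formation (adjusted p = 0.295), 0.00 for the tricarboxylic acid cycle, 0.01 for sulfur, -0.06 for thiamine (mean 0.05), 0.16 for phosphate starvation, 0.01 for heat shock proteins, -0.12 for hexose transporters, -0.29 for a-cell genes and -0.18 for sporulation genes. The medians of the thiamine, iron, decapping, ribosome biogenesis, hexose and sporulation lists were positive with the same total, and those of translation factors, sulfur and heat shock proteins negative after quantile normalization. The camera test ran downward for the tricarboxylic acid cycle, sulfur and heat shock lists against medians of 0.00, 0.01 and 0.01, and upward for thiamine.

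The genes enriched in both media overlapped. Of 270 genes higher in YEPD, 197 were also higher in minimal medium, where 38.4 were expected (Fisher's exact test p = 1.88e-114), and of 30 lower 21 were shared (4.39 expected, p = 8.96e-12 by the same test). Both contrasts use the same estimate of spread per gene and share a trend with gene length. The expected counts and p-values, which take the calls as independent, thus cannot measure how far the overlap exceeds chance. No gene (0) was called in opposite directions by limma, and changes in both media were related across genes, which are not independent replicates (Pearson 0.711, Spearman 0.731). Overlap of genes higher after ADPRC in the 2 media came to 119, 125 and 120 without minimal ADPRC replicates 1, 2 and 3, and 86, 103 and 131 without YEPD mock replicates 1, 2 and 3, with 0 to 3 shared lower in these. They numbered 147, 137 and 145 without minimal mock replicates 1, 2 and 3, with 4, 4 and 6 lower. Without the unnumbered YEPD ADPRC library, replicate 2 and replicate 3 there were 213, 265 and 398 shared higher and 69, 61 and 349 shared lower. Shared genes higher and lower were 40 and 0 when only the groups compared were fitted, 373 and 209 with weights per library, 98 and 1 with edgeR, 145 and 12 with DESeq2, and 73 and 16 with the trend in gene length removed. In both media the change ran with gene length. Genes higher in minimal medium had a median coding length of 717 bp and those lower 2533.5 bp, and in YEPD 675.5 and 2295 bp, against 1269 bp for all tested genes (rank correlation across genes -0.679 and -0.690).

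**Figure D4:**
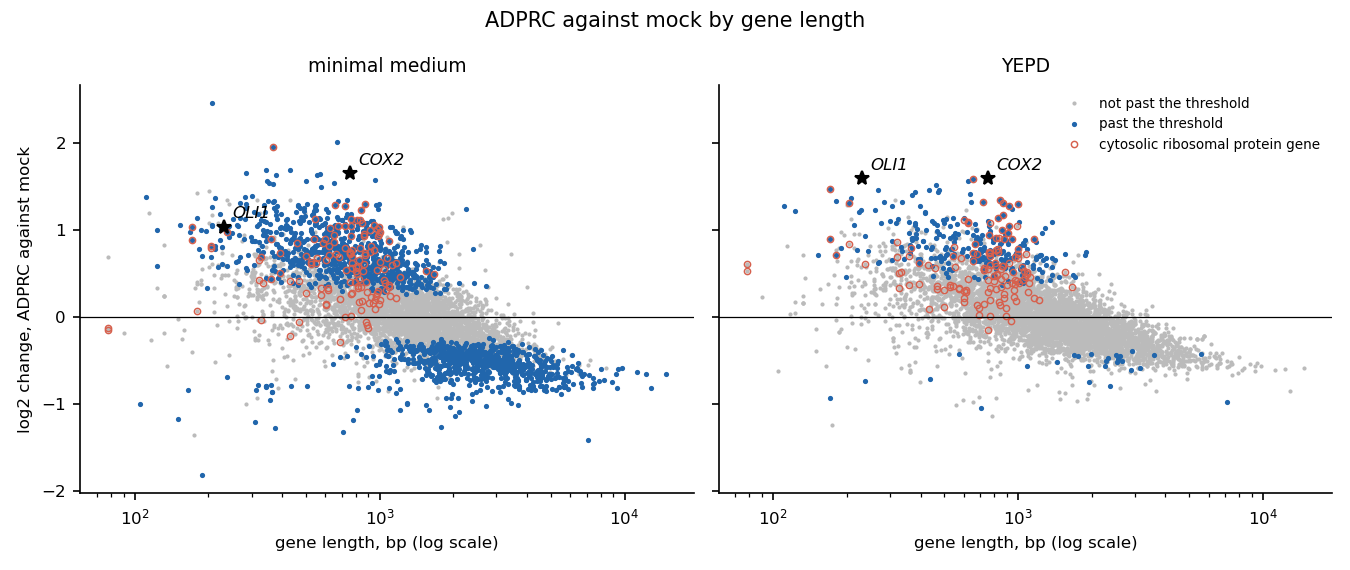
Log2 change of ADPRC against mock (y axis) against gene length in bp (x axis, log scale) for each tested gene in minimal medium and in YEPD; blue points are past the threshold, gray points are not, red circles are cytosolic ribosomal protein genes and stars are COX2 and OLI1. Short genes lie higher than long ones in both media.

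To ask whether enrichment by the enzyme depended on the medium, the difference between both ADPRC effects was tested gene by gene. COX2, OLI1 and the other mitochondrial genes, ribosomal protein genes and every other gene had a difference short of the threshold: limma called 0 genes higher and 0 lower (462 at an unadjusted p under 0.05, smallest adjusted p = 0.159), edgeR 0 and 0 (330 unadjusted) and DESeq2 0 and 0 (236 unadjusted). No list was called by camera. The smallest adjusted p, 0.282, was that of alpha-cell genes (median 0.43), oxidative phosphorylation (0.16) and glycolysis (-0.15, or 0.09 with the same total). Adjusted over the list alone, 3 mitochondrial ribosomal protein genes were lower in minimal medium relative to YEPD and 1 alpha-cell gene higher. The count of 0 rests on 1 library, since without YEPD ADPRC replicate 2 the difference was past the threshold for 492 genes higher and 556 lower. Among these were 58 cytosolic ribosomal protein genes higher and 3 lower and 4 mitochondrially encoded genes lower, and the rank correlation of the difference with gene length across genes was then -0.459. Weights per library gave 534 higher and 587 lower.

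To see how the RNA recovered without the enzyme differed between the media, mock libraries of minimal medium were compared with those of YEPD. Phosphate starvation genes were lower in minimal medium as a group, with 0 higher and 12 lower of 14 (the same adjusted over the list alone; median -1.42, camera adjusted p = 3.11e-08, and 0.00268 with an estimated correlation). The transporter gene PHO84 (YML123C) went from 2851 ± 205 in YEPD to 429 ± 18.2 (-2.73 ± 0.14, adjusted p = 3.17e-09), and the polyphosphate synthesis genes VTC4 and VTC3 fell by 1.39 ± 0.10 and 1.80 ± 0.15, though VTC4 was at -0.14 with the same total (adjusted p = 0.257). Sulfur and methionine genes were higher, with 13 higher and 2 lower of 24 (16 and 2 adjusted over the list alone; median 0.64, adjusted p = 4.31e-12, and 0.00268 with an estimated correlation). The methionine synthase gene MET6 (YER091C) rose from 2848 ± 75.4 to 11690 ± 465 (2.04 ± 0.11, adjusted p = 4.38e-09) and SAM1 by 0.74 ± 0.17. Iron uptake genes had 11 higher and 3 lower of 19 (11 and 4 adjusted over the list alone; median 0.62, adjusted p = 6.45e-07, and 0.0434 with an estimated correlation). They include the iron oxidase and permease genes FET3 (1026 to 2827, 1.46 ± 0.09) and FTR1 (1.51 ± 0.13) and the cell wall protein gene FIT3 (1.16 ± 0.13). Hexose transporter genes split, with 3 higher and 9 lower of 14 (the same adjusted over the list alone; median -2.42, adjusted p = 0.0404, and 0.221 with an estimated correlation). With a mean of at least 50, which left 7 members, the median was 0.0730 and the call ended (3 higher, 2 lower, adjusted p = 0.0885). The low-affinity carriers HXT1 and HXT3 rose by 1.04 ± 0.10 and 0.58 ± 0.12. The directions of these 4 lists held under each scaling tried.

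Lower in minimal medium were the alpha-agglutinin gene SAG1 (3542 to 1115, -1.67 ± 0.13), MF(ALPHA)2 (-1.72 ± 0.12) and the a-factor receptor gene STE3 (-0.58 ± 0.10, or 0.66 with the same total). The alpha-cell list had 0 higher and 3 lower of 7 (the same adjusted over the list alone; median -0.38, which turned positive with the same total; adjusted p = 0.0293, 0.0511 without minimal mock replicate 3, and 0.221 with an estimated correlation). The meiotic genes NDT80 (3.46 against 43.7, -3.91 ± 0.59), HOP1 (-2.93 ± 0.56) and IME1 (-1.54 ± 0.22, or -0.33 with the same total, adjusted p = 0.193) fell, making 0 higher and 3 lower of 5 sporulation genes (the same adjusted over the list alone; median -1.54, adjusted p = 0.102). The NDT80 value in minimal mock libraries lay under their floor of 3 reads, so the size of its fall is uncertain. For these meiotic genes, too, a difference in counting between the media cannot be told apart from the medium, since an antisense transcript may lack annotation. Cytosolic ribosomal protein genes had 24 higher and 0 lower (21 and 0 adjusted over the list alone, counts given after this as alone; median 0.23, adjusted p = 3.74e-15, and 0.375 with an estimated correlation). Their mean was 0.57. RPL43A, RPL36B, RPL22A, RPL33A, RPL28 and RPL39, higher by 5.49 to 7.56, have an opposite-strand neighbour not in RefSeq and are uncertain. Glycolysis and ethanol formation had 6 and 0 (the same alone; 0.34, adjusted p = 5.22e-06, and 0.244 estimated). Heat shock proteins, with SSA1 at 0.75 ± 0.13, had 6 and 1 (the same alone; 0.09, adjusted p = 0.000216, and 0.221 estimated), or 3 higher without minimal mock replicate 2 or YEPD mock replicate 2. Ribosome biogenesis had 2 higher and 28 lower of 44 (3 and 29 adjusted over the list alone; median -0.44, which turned positive with the same total; adjusted p = 0.00617, and 0.221 estimated), with 15 lower without YEPD mock replicate 1. Amino acid biosynthesis had 9 and 7 (the same alone; 0.00, adjusted p = 0.0227, and 0.349 estimated), and a median near 0 whose sign changed without minimal mock replicate 1 (-0.02), 2 (-0.01) or YEPD mock replicate 2 (-0.01). The isopropylmalate isomerase gene LEU1 rose by 1.12 ± 0.10. Mitochondrial ribosomal proteins had 11 and 1 (7 and 1 alone; 0.02, adjusted p = 0.000362, and 0.349 estimated), or 6 higher without minimal mock replicate 3 or YEPD mock replicate 1 and 7 without YEPD mock replicate 2, with a median of -0.03 without minimal mock replicate 1 and -0.02 without YEPD mock replicate 1. Histones had 1 and 0 (0 and 0 alone; 0.37, adjusted p = 0.0101, and 0.421 estimated). Thiamine metabolism was not called by camera (0 and 6 of 18, the same alone; -0.43, adjusted p = 0.114), though the thiamine transporter gene THI7 fell (-1.28 ± 0.13, or -0.04 with the same total, adjusted p = 0.757). Neither was oxidative phosphorylation (1 and 7, the same alone; -0.26), with NDE1 at -0.92 ± 0.11, or 0.33 with the same total. Also without a call were a-cell genes (0 and 2 of 3, 0 and 3 alone; -1.02) and mitochondrially encoded genes (0 and 2, the same alone; -0.56). The others were translation factors (2 and 4, the same alone; -0.04, mean 0.32), the tricarboxylic acid cycle (1 and 2, the same alone; -0.07), NAD biosynthesis (2 and 3, or 2 and 2 alone; -0.12) and decapping and 5'-to-3' decay (2 and 4, the same alone; -0.18). The test ran upward in these last 4 against a median below 0. The medians of every list without a call but the sporulation list turned positive with the same total.

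The widest differences between media lay at genes that overlap other annotated frames or have near-identical copies, and are uncertain. HYP2 (YEL034W), a translation factor eIF5A gene, had 2908 ± 37.2 normalized counts in minimal mock libraries and 0 in all YEPD libraries, at least 900.4-fold higher. The metallothionein genes CUP1-1 and CUP1-2, with identical values, had 2965 ± 106 against 2.42 ± 2.34 (10.08 ± 0.47), and the ribosomal protein genes RPL43A (2653 against 13.2) and RPL36B (2881 against 15.1) rose by 7.56 ± 0.26 and 7.55 ± 0.25. Lower by the most were ribosomal DNA frames, YLR154W-F (-12.57), TAR1 (-12.12, 761 against 3334520), YLR154W-A (-11.98), YLR154W-E (-11.79) and YLR154W-B (-11.78). Among genes with no overlap-prone neighbour, chosen after their values were seen, the zinc transporter gene ZRT1 rose from 84.5 ± 4.62 to 2442 ± 33.1 (4.84 ± 0.22, adjusted p = 8.24e-10), the phospholipid methyltransferase gene OPI3 by 4.02 ± 0.17, the zinc-regulated ZPS1 by 3.85 ± 0.16, SAM2 by 2.50 ± 0.15 and FIT2 by 2.30 ± 0.16. In the other direction stood YLR264C-A (-7.29), YFL067W (-6.94), YFL068W (-6.35), and the meiotic genes IME4 and SPO75, 0 in minimal mock libraries and at least 35.1-fold and 16.3-fold lower than in YEPD. The choice sees annotated neighbours only. For these lower genes a difference in counting between the media cannot be told apart from the medium, since an antisense transcript may lack annotation.

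In mock libraries 400 genes were higher and 1228 lower in minimal medium, of which 154 and 262 changed over 2-fold, and the median of all genes was -0.20. The balance of directions rests on the scaling, with 651 higher and 494 lower after TMM, 5006 and 162 with the same total (median of all genes 1.03) and 580 and 546 after quantile normalization. The same total includes the ribosomal DNA frames, whose share was 52.9% in minimal mock and 80.8% in YEPD mock libraries. The number lower was 761 without YEPD mock replicate 1 and 757 without replicate 2, and stayed within 1.5 times the full count without each other mock library. On recovered reads edgeR gave 423 higher and 329 lower and DESeq2 427 and 318. Leaving out genes that can overlap another on the opposite strand gave 163 and 1016, fewer being tested. Fitting only the mock libraries gave 668 and 1966, weights per library 657 and 2029, and removal of the trend in gene length 879 and 546. Relative to the median of all genes, the phosphate, sulfur, iron and hexose lists kept their directions in each scaling.

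**Figure D5:**
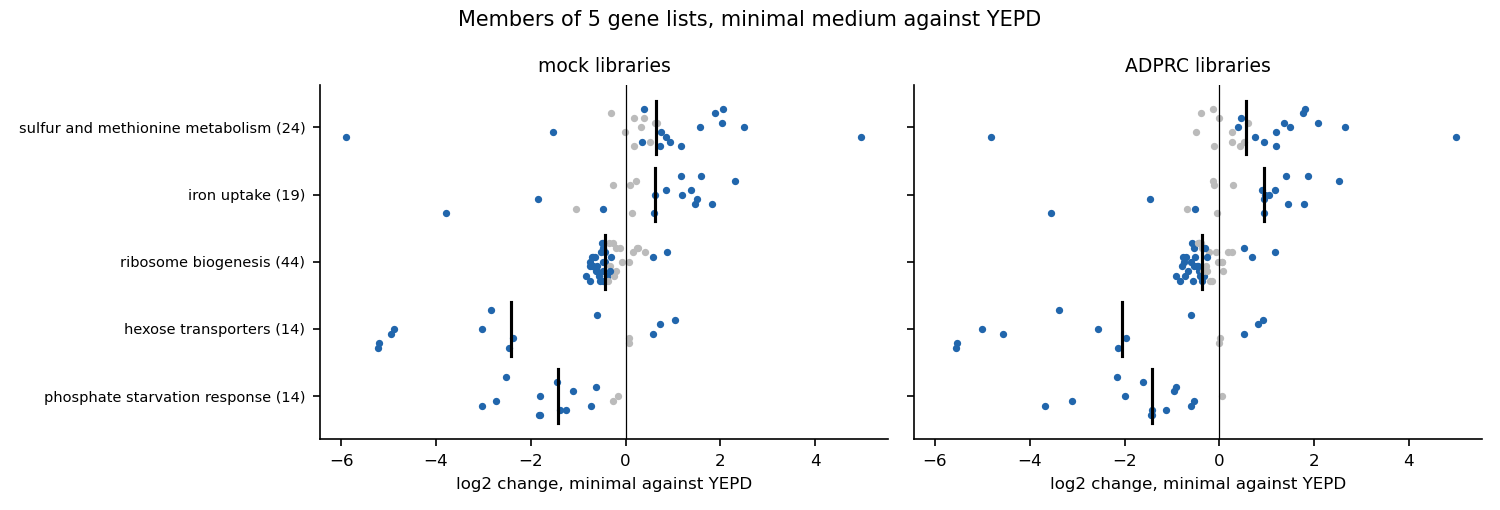
Log2 change of minimal medium against YEPD (x axis) of each member of 5 gene lists, with the number of members in parentheses, in mock and in ADPRC libraries; blue points are past the threshold, gray points are not, and a black tick marks the median. Sulfur and iron genes lie mostly above 0 and phosphate, ribosome biogenesis and most hexose transporter genes below it, of which ribosome biogenesis in both panels and phosphate in ADPRC libraries turn positive with the same total per library.

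Media were compared in ADPRC libraries in the same way. Phosphate genes had 0 higher and 13 lower of 14 (the same adjusted over the list alone; median -1.42, or 0.06 with the same total; camera adjusted p = 4.57e-08, and 0.00344 with an estimated correlation). PHO84 went from 2274 to 258 (-3.11 ± 0.14, adjusted p = 6.61e-10), with VTC3 at -1.98 ± 0.15 and VTC4 at -1.41 ± 0.10, or 0.07 with the same total. Sulfur genes had 13 higher and 1 lower of 24 (15 and 2 adjusted over the list alone; median 0.57, adjusted p = 2.90e-11, and 0.00344 estimated), with MET6 at 2.08 ± 0.11. Iron genes had 11 higher and 3 lower of 19 (the same alone; median 0.94, adjusted p = 4.37e-07, and 0.0405 estimated), with FET3 at 1.44 ± 0.09, FIT3 at 1.41 ± 0.13 and FTR1 at 0.94 ± 0.13. HXT1 (0.93 ± 0.10), LEU1 (1.13 ± 0.10) and SSA1 (0.96 ± 0.13) rose again, and SAG1 (-1.71 ± 0.13), MF(ALPHA)2 (-1.80) and THI7 (-1.17 ± 0.13) fell. With the same total these were -0.22 (adjusted p = 0.106), -0.32 (0.0519) and 0.31 (0.0227). The largest by size were HYP2 at 2757 ± 145 against 0 in YEPD (at least 978-fold higher), CUP1-1 and CUP1-2 (10.63), RPL43A (8.11) and RPL36B (8.09). At the other end stood YLR154W-F (-14.32), YLR154W-A (-13.53), RRT15 (-13.44), YLR154W-B (-13.44) and TAR1 (-13.05). Among genes with no overlap-prone neighbour, chosen after their values were seen, ZRT1 (112 to 3839, 5.17), ZPS1 (4.35), OPI3 (4.04), SAM2 (2.65) and FIT2 (2.52) rose. Those that fell were IME4 (186 to 0.383), the phenylpyruvate decarboxylase gene ARO10 (242 to 1.98, -6.44), YLR264C-A (-7.59), YFL067W (-6.31) and YFL068W (-6.24). For these, too, a difference in counting cannot be told apart from the medium.

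Some camera calls in ADPRC libraries were lost with an estimated correlation, and counts adjusted over the list alone are given after this as alone. Cytosolic ribosomal proteins had 16 higher and 1 lower (15 and 0 alone; median 0.20, adjusted p = 1.82e-13, and 0.394 estimated), with 106 higher and 3 lower without YEPD ADPRC replicate 2. Their median was 0.48 without that library, 0.08 without the unnumbered YEPD ADPRC library and 0.05 without YEPD ADPRC replicate 3. Their mean was 0.57, and RPL43A, RPL36B, RPL22A, RPL33A, RPL28 and RPL39, uncertain for their opposite-strand neighbours, were higher by 5.69 to 8.11. Mitochondrial ribosomal proteins had 7 and 2 (6 and 2 alone; 0.02, adjusted p = 0.000958, and 0.394 estimated), with a median of -0.01 without the unnumbered YEPD ADPRC library and -0.04 without YEPD ADPRC replicate 3. Without YEPD ADPRC replicate 2 they had 19 higher and a median of 0.08. Glycolysis and ethanol formation had 5 and 1 (5 and 0 alone; 0.21, adjusted p = 0.00271, and 0.394 estimated), with 13 higher and a median of 0.50 without that library. The median was 0.03 without the unnumbered YEPD ADPRC library and 0.07 without YEPD ADPRC replicate 3. Heat shock proteins had 5 and 1 (the same alone; 0.08, adjusted p = 0.00213, and 0.394 estimated), with 12 higher and a median of 0.28 without YEPD ADPRC replicate 2. Their median was 0.02 without the unnumbered YEPD ADPRC library, 0.05 without YEPD ADPRC replicate 3, and 0.0055 and 0.23 without minimal ADPRC replicates 2 and 3. Amino acid biosynthesis had 10 and 8 (11 and 9 alone; -0.01, mean 0.05, adjusted p = 0.0339, and 0.394 estimated), a median that turned positive with TMM, the same total and quantile normalization and without minimal ADPRC replicate 1 (0.0051) or YEPD ADPRC replicate 2 (0.03), and the call ended without the unnumbered YEPD ADPRC library (adjusted p = 0.101). Ribosome biogenesis had 3 and 25 (3 and 29 alone; -0.37, positive with the same total; adjusted p = 0.0339, and 0.394 estimated), and the call ended without YEPD ADPRC replicate 3 (0.0512). Hexose transporters had 3 and 9 (the same alone; -2.06, the same with HXT15 and HXT16 at their bounds; adjusted p = 0.0459, and 0.259 estimated), and the call ended without minimal ADPRC replicate 3 (0.0834) or YEPD ADPRC replicate 2 (0.226). With a mean of at least 50 their median was 0.0203 (7 members, 3 higher, 2 lower, adjusted p = 0.125). Thiamine metabolism (0 and 7, the same alone; -0.59, adjusted p = 0.0915), NAD biosynthesis (2 and 3, 2 and 1 alone; 0.06, adjusted p = 0.0754) and mitochondrially encoded genes (0 and 2, 0 and 5 alone; -0.70, adjusted p = 0.182) were not called. Likewise not called were a-cell genes (0 and 3, the same alone; -0.91), sporulation genes (0 and 3, the same alone; -0.81), histones (1 and 0, 0 and 0 alone; 0.21) and alpha-cell genes (0 and 2, the same alone; -0.06). The rest were translation factors (2 and 7, 2 and 3 alone; -0.10, mean 0.31), oxidative phosphorylation (2 and 7, 1 and 5 alone; -0.08), the tricarboxylic acid cycle (1 and 2, 0 and 2 alone; -0.01) and decapping and 5'-to-3' decay (2 and 3, the same alone; -0.18). The test ran upward in these last 4, as for amino acid biosynthesis, against a median below 0. With the same total every negative median among the lists not called turned positive.

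In ADPRC libraries 387 genes were higher and 1411 lower in minimal medium (162 and 258 over 2-fold), the median of all genes being -0.19. The balance rests on the scaling here too, with 636 and 454 after TMM, 5192 and 139 with the same total (median 1.28) and 598 and 617 after quantile normalization. Counts higher and lower were 1011 and 2162 without YEPD ADPRC replicate 2, 287 and 773 without the unnumbered library, 298 and 800 without YEPD ADPRC replicate 3, and 283 and 841, 297 and 830, and 299 and 1044 without minimal ADPRC replicates 1, 2 and 3. On recovered reads edgeR gave 534 and 482 and DESeq2 527 and 461. Without genes that can overlap another on the opposite strand there were 155 and 1169, fewer being tested. Fitting only the ADPRC libraries gave 264 and 683, weights per library 1111 and 2466, and removal of the trend in gene length 763 and 485.

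The genotype of the strain was visible in the table. LEU2, LYS2 and URA3, deleted in BY4742, were 0 in all 12 libraries, while HIS3, whose deletion in this background leaves part of the gene, had means of 101.5 and 141 in minimal mock and ADPRC and 111 and 183 in YEPD mock and ADPRC libraries. The alpha-factor gene MF(ALPHA)1 had group means of 2448 to 4657, and the a-factor genes MFA1 and MFA2 had group means of 4.49 normalized counts or less. MATALPHA1 and HMLALPHA1, copies of the same sequence, had identical values and are uncertain.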

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

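The trend with gene length and the genes that can overlap another were taken up as alternatives only after the data were seen, and all other alternatives were planned. Of the values of single genes named in the report under alternatives, 2443 kept their direction and side of the threshold, 146 kept the direction but ended the call, 16 became calls and 6 reversed. Unless a cause is given, the cause was not tested. Depth limits the genes near the floors of 3 reads, up to 5.42 normalized counts, HUG1 and SHU2 among them.

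With an estimated correlation between genes in camera, the adjusted p of these lists passed 0.05 while the medians stayed as they were, since only the test changes. In minimal medium after ADPRC these were cytosolic ribosomal proteins (0.60), mitochondrial ribosomal proteins (0.31) and oxidative phosphorylation (0.41), and in YEPD the same lists (0.53, 0.27 and 0.18) and histones (0.60). In the comparison of media in mock libraries they were cytosolic ribosomal proteins (0.23), mitochondrial ribosomal proteins (0.0151), glycolysis (0.34), amino acid biosynthesis (0.00256), heat shock proteins (0.0937), ribosome biogenesis (-0.44), histones (0.37), hexose transporters (-2.42) and alpha-cell genes (-0.38). In ADPRC libraries they were cytosolic ribosomal proteins (0.20), mitochondrial ribosomal proteins (0.0204), glycolysis (0.21), amino acid biosynthesis (-0.0106), heat shock proteins (0.0785), ribosome biogenesis (-0.37) and hexose transporters (-2.06). The phosphate, sulfur and iron lists stayed called in both.

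Keeping genes with a mean of at least 50 reversed the hexose transporter medians, to 0.0730 in mock and 0.0203 in ADPRC libraries, as fewer members were tested. TMM factors gave 651 genes higher and 494 lower between media in mock libraries, and 636 and 454 in ADPRC libraries. With the same total per library, 2492 genes were higher and 51 lower after ADPRC in minimal medium, 2 were lower in YEPD and 2 lower in both. Between media 5006 were higher and 162 lower in mock and 5192 and 139 in ADPRC libraries. That setting reversed NDE1 (0.33), STE3 (0.66) in mock libraries, THI7 (0.31) and VTC4 (0.0741) in ADPRC libraries, and KGD1 after ADPRC in minimal medium (0.0314). It multiplies every value of a library by 1 factor, taken from a total that includes the ribosomal DNA frames. Their share was 52.9% in minimal mock, 31.7% in minimal ADPRC, 80.8% in YEPD mock and 75.2% in YEPD ADPRC libraries, so differences in that share shift every gene. Quantile normalization left 50 genes lower in YEPD after ADPRC, 546 lower between media in mock libraries, and 598 higher and 617 lower in ADPRC libraries. It put amino acid biosynthesis at 0.11 in mock libraries, no longer called, and at 0.0731 in ADPRC libraries, reversed.

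Fitting only the groups compared gave 1291 higher and 1259 lower in minimal medium, 46 and 0 in YEPD, 40 shared higher and 0 shared lower. Between media it gave 668 and 1966 in mock libraries and 683 lower in ADPRC libraries. The replicate block, for which no source says that equal numbers belong together, gave 472 higher and 347 lower in minimal medium, 26 and 0 in YEPD, 25 shared higher and 0 shared lower, and 613 lower between media in ADPRC libraries. It ended the calls of hexose transporters in mock libraries (-2.42) and amino acid biosynthesis in ADPRC libraries (-0.0561). It also ended the calls of KGD1 in minimal medium (adjusted p = 0.057) and of genes named in YEPD (0.0625 to 0.198), namely HHT2, HTB2, MF(ALPHA)2, RPL37B, MAK31, DIB1, YJR112W-A and the 10 decreases. Of the cytosolic ribosomal protein genes 6 were then higher in YEPD. Correlations of residuals between libraries of equal number were -0.02, -0.09 and -0.06 for ADPRC and mock in minimal medium and -0.04 and -0.15 in YEPD. Across media they were -0.05, -0.02 and -0.01 for mock and 0.32 and 0.22 for ADPRC libraries, where pairs of unequal number lay between -0.30 and 0.29. The unnumbered YEPD ADPRC library was left unpaired in the block. Its correlation was 0.03 with YEPD mock replicate 1 and 0.03 with minimal ADPRC replicate 1.

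Weights per library gave 1364 higher and 1360 lower in minimal medium, 532 and 283 in YEPD, 373 and 209 shared, and 534 and 587 for the difference between media. Between media they gave 657 and 2029 in mock and 1111 and 2466 in ADPRC libraries. Without trend and robust estimation 15 genes were lower in YEPD, 7 were shared lower, and 3 were higher in the difference between media. On recovered reads, without YEPD mock replicate 2, edgeR gave 131 higher and 3 lower in YEPD, 98 and 1 shared, and 329 and 482 lower between media in mock and ADPRC libraries. DESeq2 gave 15 lower in YEPD, 12 shared lower, and 318 and 461 lower between media.

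With the length trend removed, 389 genes were higher and 425 lower in minimal medium after ADPRC, 144 higher in YEPD, 73 shared higher and 1 lower in the difference between media. Between media 879 were higher and 546 lower in mock and 763 and 485 in ADPRC libraries. COX1 reversed in minimal medium (0.14), its length being a span with introns. The calls of mitochondrial ribosomal proteins (0.0203) and oxidative phosphorylation (-0.00332) ended in minimal medium, as did those of mitochondrial ribosomal proteins (-0.0197), oxidative phosphorylation (-0.12) and histones (0.18) in YEPD. Between media mitochondrial ribosomal proteins (0.0623) and histones (0.30) were no longer called in mock libraries, nor mitochondrial ribosomal proteins (-0.0170) and ribosome biogenesis (-0.13) in ADPRC libraries, where amino acid biosynthesis turned positive (0.18). Without genes that can overlap another, 163 genes were higher between media in mock and 155 in ADPRC libraries, fewer genes being tested. Mitochondrial ribosomal proteins (-0.0393) and amino acid biosynthesis (-0.0177) then reversed in mock libraries, and mitochondrial ribosomal proteins (-0.000498) in ADPRC libraries.

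Leaving out 1 library at a time, the genes higher ranged from 337 to 543 and those lower from 211 to 469 in minimal medium after ADPRC, from 107 to 617 and from 0 to 492 in YEPD, and from 0 to 492 and from 0 to 556 for the difference between media. Shared genes ranged from 86 to 398 higher and from 0 to 349 lower. Between media 757 to 918 were lower in mock libraries, and 283 to 1011 higher and 773 to 2162 lower in ADPRC libraries. Medians ranged from -0.0382 to 0.34 for oxidative phosphorylation in YEPD. In mock libraries they ranged from -0.0333 to 0.0205 for mitochondrial ribosomal proteins, from -0.0215 to 0.0196 for amino acid biosynthesis and from -0.51 to -0.37 for alpha-cell genes. In ADPRC libraries they ranged from -0.0400 to 0.0782 for mitochondrial ribosomal proteins, from -0.0603 to 0.0256 for amino acid biosynthesis, from -0.39 to -0.34 for ribosome biogenesis and from -2.19 to -1.91 for hexose transporters.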

Other observations

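The tests of the read strand, of medium alone, of depth, of label and of capture were chosen only after the result was seen, as were those of COX2, OLI1, all called genes and capping by length. The tests of ribosomal protein genes and of the length trend in YEPD ADPRC replicate 2 were chosen before, and the splits of libraries were planned.

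Differences between media of over 30-fold had several forms. Of the reads of YEPD mock libraries, 62.3% fell on the Watson-strand frames of the ribosomal DNA, TAR1, RRT15 and the YLR154W frames, against 0.0383% in minimal mock libraries. The Crick-strand frame YLR154C-G took 18.5% and 52.9%. Medium alone, with the same counting, would move both strands of this repeat together, while the ratio of their folds was 4671, which argues against it at these frames. Outside the ribosomal DNA, 36 matched genes differed over 32-fold in mock libraries. Of the 19 higher in minimal medium, 18 had an opposite-strand neighbour not in RefSeq, a share 6.06 times that of all tested genes, 15.6% (Fisher's exact test p = 4.33e-14). Counting by strand in minimal but not in YEPD libraries is a candidate explanation for these, HYP2 and RPL43A among them, and a difference in library preparation is not excluded. Of the 17 lower in minimal medium 3 had such a neighbour, 1.129 times the share of all tested genes (Fisher's exact test p = 0.74). For these 17 genes a difference in counting cannot be told apart from the medium, since an antisense transcript needs no annotated neighbour and the genes are few.

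Short genes were higher and long genes lower after ADPRC in both media. Depth as the cause is argued against in YEPD. Without ADPRC replicate 2 the ADPRC libraries there had 0.976 times the reads of mock libraries, and 1.02 times outside the ribosomal DNA (1.31 with that library), while the rank correlation of change with length was -0.4545 (-0.690 with it). In minimal medium, where ADPRC libraries had 2.07 times the reads, depth stays open. Recovery by length as the whole cause is argued against by COX2, which kept 1.325 ± 0.20 in minimal medium and 1.35 ± 0.20 in YEPD with the trend removed. OLI1 in YEPD (1.12 ± 0.24, adjusted p = 0.034) argues against it as well. Of all genes called, 39.51% of those higher and 31.69% of those lower in minimal medium and 46.67% of those higher in YEPD stayed called. The calls of the other genes ended. Medians of these 3 sets went from 0.73 to 0.44, from -0.53 to -0.22 and from 0.78 to 0.54. These shares cannot decide the question, since genes picked as called stay so in part by that choice. The coding length is also not the length of the RNA. Of the 6 genes lower in YEPD that are shorter than the median, 50% stayed called (median -0.72 to -1.16 ± 0.16). All 6 changes grew, but the removal itself enlarges the fall of a short gene. Their fall runs against the trend, so recovery by length alone would not give it, though the 6 genes are few and picked as lower. The call of SCEI, among them, ended with the trend removed (adjusted p = 0.071), and its frame in an intron need not have the length of its RNA. Of the 21 longer genes lower in YEPD 4.762% (1) stayed called, and their median went from -0.50 to -0.28 ± 0.04. For these recovery by length as the whole cause cannot be told apart from other causes, since genes picked for low values stay low in part by that choice. For cytosolic ribosomal proteins the median went from 0.60 to 0.2589 (0.20 for the 80 genes whose span is a multiple of 3 and 0.37 for the other 57, many with introns that inflate the length). For OLI1 in minimal medium the change went from 1.04 ± 0.15 to 0.5178 ± 0.24, where the wider error and smaller change ended the call. Recovery by length cannot be told apart from enrichment for the ribosomal protein genes, whose median lay between the bounds set beforehand though the list kept its camera call with the preset correlation, nor for OLI1 in minimal medium. More capping of short RNAs would give the same rank correlation (-0.6786 in minimal medium) and may also hold, since no library here separates capping from length.

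YEPD ADPRC replicate 2 lay apart from the other two libraries of its group. Lower depth is argued against by its reads, 1.158 times those of the shallower of the others. Stronger capture cannot be judged from its COX2 value, 0.8711 times the lower of theirs, since mitochondrial RNAs that fell after ADPRC were also lower there. COX1 was at 229 in that library against 458 (unnumbered) and 536 (replicate 3), and COX3 at 89.5 against 246 and 236. A library of minimal-medium cells under a YEPD label cannot be judged from its correlations, 0.8739 at most with minimal ADPRC libraries and 0.935 to 0.943 with YEPD mock libraries. A difference in counting between the media could set these whatever the cells. ZRT1 and MET6, with no overlap-prone neighbour, argue against such a label, though these genes are few. Across YEPD ADPRC libraries they were at 112 ± 53.4 and 2808 ± 228, against 3839 ± 360 and 11858 ± 95.5 in minimal ADPRC libraries (SD). The slope of log2 value per doubling of length was -0.274 in YEPD ADPRC replicate 2 against 0.0619 and 0.104 in the others. Removing the trend lowered the ratio of its distance from them over the distance between them from 2.238 to 1.762, so a different length trend could be part of it and stays open as the whole.

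For the genes past the threshold, the splits are too few for a share under 0.05: 1 of 10 splits of the 6 libraries gave as many genes as the real one in minimal medium (1583, highest other 0), in YEPD (300, highest other 0), between media in mock libraries (1628, highest other 0) and between media in ADPRC libraries (1798, highest other 657). For the difference between media the real split gave 0 genes, which all 100 splits drawn reach, so their share says nothing. The highest other gave 1173. It exchanged the treatments of all 6 minimal libraries and of 2 YEPD libraries, so the treatment itself is a structure of the samples that it takes up.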
